A study of Mus musculus with 8 samples.

How the data were processed

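Gene expression was measured in 8 samples of mouse cells at day 6 of a neural induction that turns embryonic stem cells (ESC) into neural progenitor cells (NPC), which the labels call RGC-like. The labels name 4 samples as control and 4 as knockdown, and the series' design text says that the cells carried a control short hairpin RNA or one against Zrf1. Per the labels, each sample contributed 100 ng of RNA, which was amplified with an oligo-dT primer and T7 polymerase and labelled with Cy3, so each array has 1 colour and 1 sample. The oligo-dT step captures polyadenylated RNA.

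The deposited scanner files hold the intensity of each spot on Agilent mouse arrays of design 028005 with probes of 60 bases. Per the file headers, the intensity was extracted with Agilent Feature Extraction 10.7.3.1, corrected for background and spatial trends within each array, and given as a small positive substitute value where a spot was dim. Nothing had been scaled between arrays in these columns. The authors' own value table holds log2 values of the same arrays. Its 8 columns share 1 distribution, with a median of 7.10 in every column, and each correlated at 0.99999, rounded to 5 decimals, across probes with a normexp background correction (offset 50) and quantile normalization of the mean spot intensities computed here, from which it lay on average 0.0358 away. The steps the authors took to make that table, including any background offset, are not given in the sources used here, so its log2 values were used as an alternative only.

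Each array carried 59305 spots that were not controls. Between 53.4% and 60.3% of them were well above background, none was saturated, and the 75th percentile of the processed signal lay between 483 and 696 intensity units. The number of arrays, 8, limits the precision of every comparison. A probe that was not well above background on any array of a group has only a bound there. Its fold is then given as "at least", from the mean of the brighter group against the mean, per array of the dim group, of the higher of the probe's own signal and the lowest signal among probes well above background. The limma p of such a probe uses its dim signals and their spread as they are, so it is not a p for that bound.

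From the processed intensities, spots of a probe were averaged after outlier spots were removed, log2 was taken, and the 75th percentile of each array was subtracted. A log2 signal of 0 is therefore the 75th percentile of that array, and log2 signals of different probes are not compared. Of 55681 probes, the 29091 that were well above background on all arrays of at least 1 group were tested. Where a gene had several such probes, the one with the highest mean over the 8 arrays stood for it, which gave 21750 genes, 14655 of them with a current symbol. Probe names were updated through a RefSeq gene table: 26300 probes matched by accession, 2044 by symbol and 355 by synonym, and 26982 kept the name in the file. Zrf1 is called Dnajc2 in that table. Probe positions are those of the files, on mouse genome build mm9. The gene table is on another build, so only its chromosome names were used. After the data were seen, the chromosome of each probe was compared with that of its gene, and 50 of 14626 genes, 3 of them among 536 genes of the lists (Gapdh, Pgk1 and Gcm1), had their probe on another chromosome. They were kept under the rule fixed beforehand, and exon or UTR annotation of the probes was not analysed here.

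The comparison was knockdown against control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05 on the adjusted p. Lists of genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 28 lists, and again with an estimated correlation and with fry. The 28 lists covered pluripotency, epiblast, neural progenitor, neuron, glia, Wnt ligands and receptors, Wnt targets and antagonists, BMP and TGF-beta targets, Notch, Hedgehog, retinoic acid, Hox, forebrain and midbrain, hindbrain and spinal cord, neural crest, mesoderm, endoderm, trophoblast, fibroblast or feeder cells, endothelium and blood, epithelium, Polycomb, p53 targets, cell cycle, chaperones and stress, interferon response, ribosome biogenesis and housekeeping genes. They named 656 genes on the array, summed over lists, of which 563 were tested. Some genes stand in more than 1 list, among them 3 of the 26 tested endoderm genes. The lists, the designs, the alternatives and the rule for named genes were fixed before the data were examined. That rule takes Dnajc2, the 10 genes with the largest rise and the 10 with the largest fall among called genes with a symbol whose groups did not overlap, and up to 4 called members of each list with the smallest p. Any other gene is named as an exception, chosen after its values were seen. Some genes that the rule takes are not reported here. The fit was tested on simulated data made for the comparison of 4 with 4 arrays over 21750 genes. It recovered 38% of genes changed by 0.5 on the log2 scale, 72% of those changed by 1, 96% by 2 and 98% by 3, and 11 of its 163 calls were unchanged genes. Only 50 genes were changed at each size, with noise independent between genes. These rates therefore do not describe a comparison in which 58% of genes are called. The simulated shift of 1 list was found and no unshifted list was called. Because the simulated genes were independent, this does not test camera where the genes of a list move together.

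Samples were taken from the labels. The names of the scanner files number the knockdown arrays in a way that leaves open that knockdown 1 and 2, and knockdown 3 and 4, are repeat arrays of the same culture. By a rule fixed beforehand the pairs would have been averaged if their deviations from the group mean correlated above 0.1 and above all correlations across pairs. They correlated at -0.37 and -0.31 across probes, against -0.51 to -0.03 across pairs, so each array was kept as a replicate, and the comparison of 4 with 2 is an alternative. Deviations from a mean of 4 arrays tend to correlate negatively, and the arrays of each pair lay on different slides. The rule could therefore miss repeat arrays, and a fit with the pairs as a random block gave a correlation of 0.21 within them. Nothing in the labels says that samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The arrays lay on 3 slides that each held both groups. Slide 1 held control 2 and knockdown 1, slide 2 held control 3, control 4, knockdown 2 and knockdown 3, and slide 3 held control 1 and knockdown 4. Scan followed slide.

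The alternatives changed the background correction, the scaling (median or quantile), the source of values (the authors' table), the filter on dim probes, the choice among probes of a gene, the variance model, the threshold, the set test, the blocks (slide, label number, number in the file name) and the arrays included. One alternative, the arrays of slide 2 alone, was added after the data were seen. The alternative with the number in the file name as a random block tested lists with the pre-ranked form of camera, on the limma t values. Its list results therefore differ from the others in test as well as in block. Files were read with version 1.17.8 of data.table and jsonlite 2.0.0, and figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15. Spots for controls and probes dim in both groups were left out.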

Results

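Messenger RNA of mouse cells at day 6 of neural induction was profiled on 8 single-colour arrays, 4 from control cells and 4 from cells with a short hairpin RNA against Zrf1. Zrf1, named Dnajc2 in current annotation, is a J-domain protein that acts as a ribosome-associated chaperone and also binds ubiquitylated histone H2A in chromatin. The series asks what its loss does to the identity of NPC derived from ESC. On each array between 53.4% and 60.3% of the 59305 spots were well above background. Levels are log2 signals relative to the 75th percentile of each array, given as mean ± SD (n = 4 arrays per group), and changes are knockdown minus control.

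Zrf1 knockdown at day 6 came with a broad loss of neural progenitor transcripts and a gain of transcripts typical of endoderm. Of 36 tested neural progenitor genes, 30 fell and 3 rose, among them the radial glial fatty acid binding protein Fabp7, at least 109-fold lower, and the Notch effector Hes5, 16.2-fold lower. Of 26 endoderm genes, 24 rose and 1 fell, including the fetal plasma protein Afp, at least 9.35-fold higher, and the endocytic receptor Cubn, 41.4-fold higher. The stress transcription factor Ddit3 rose 43.0-fold. Across the array 12615 of 21750 tested genes (58%) passed the limma test at an adjusted p under 0.05, 6369 higher and 6246 lower.

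The targeted gene was measured first. Its probe (A_52_P533198, designed on NM_009584) lies on chromosome 5 from 21272454 to 21272513 (mm9) and has the sequence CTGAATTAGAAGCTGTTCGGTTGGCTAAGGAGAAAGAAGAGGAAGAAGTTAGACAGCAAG. Dnajc2 had a log2 signal of 1.87 ± 0.11 in control and -2.32 ± 0.23 in knockdown arrays, a change of -4.19 (SE 0.12), which is 18.3-fold lower, with a limma adjusted p of 1.13e-07. The signal was well above background on all 8 arrays, and the lowest control array, at 1.75, lay above the highest knockdown array, at -2.08. Within the slides the change was -4.05, -4.22 and -4.27.

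**Figure D1:**
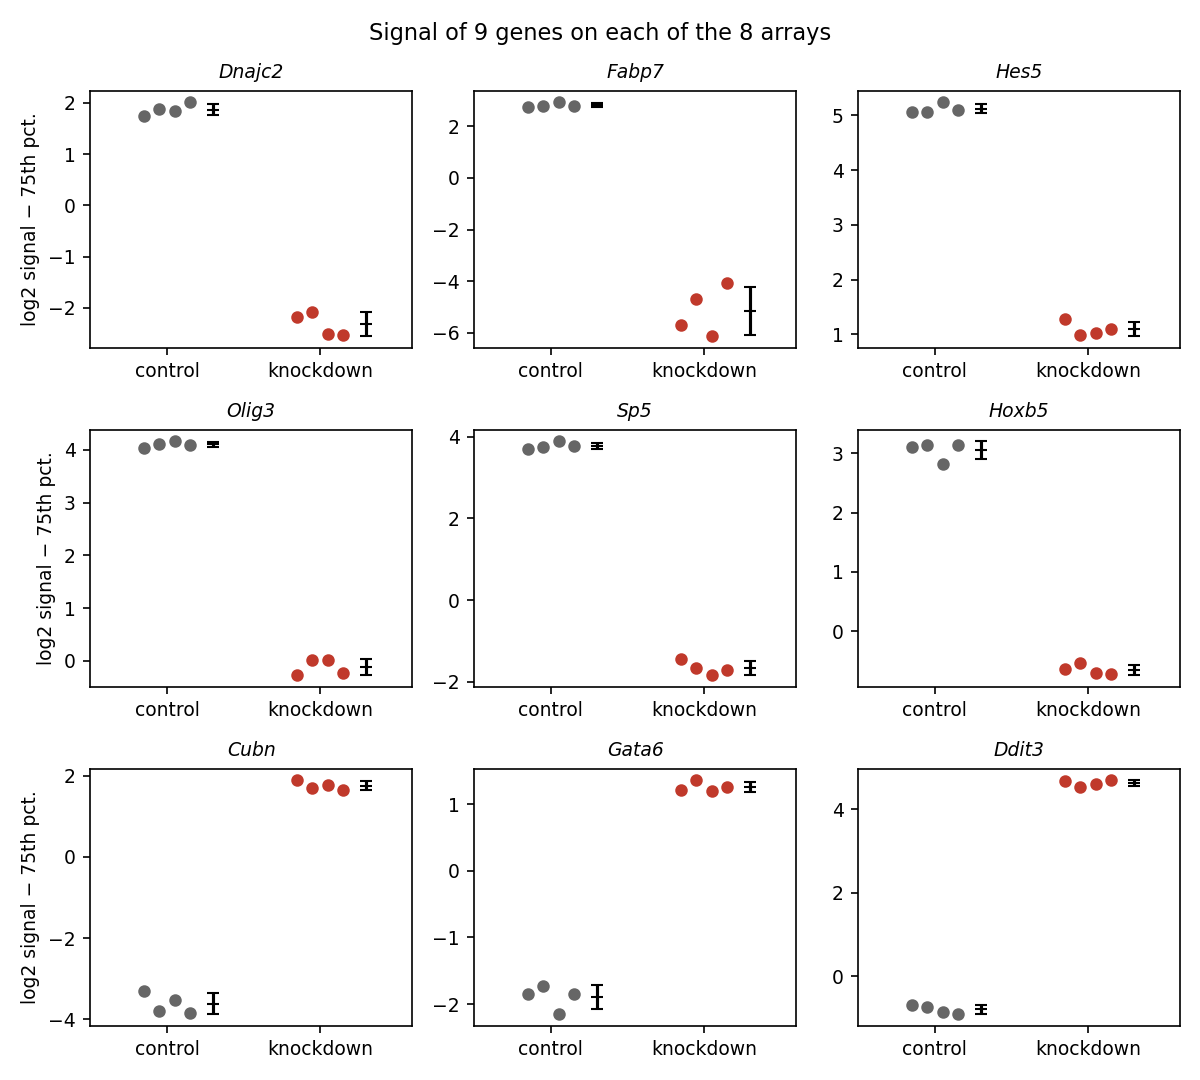
Log2 signal relative to the 75th percentile of the array for 9 genes on each of the 4 control (grey) and 4 knockdown (red) arrays, with the group mean and SD in black beside the points. Dnajc2 changed by -4.19 and Ddit3 by 5.42, Fabp7 was well above background on the control arrays alone and at least 109-fold lower in knockdown, with no overlap between the groups in any of the 9 panels.

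The change was wide as well as deep. Among the called genes, 2260 rose and 1622 fell by at least 2-fold, and 533 rose and 337 fell by at least 4-fold. All 4 arrays of one group lay above all 4 of the other for 55.0% of tested genes, where chance gives 2.86%. With slide as a block 13169 genes were called, 12340 of them also called without it, and 99.3% of the called genes had the same sign on all 3 slides. The SD of the log2 difference between a control and a knockdown array had a median of 0.95, against 0.42 between control arrays and 0.41 between knockdown arrays. Scaling by the median in place of the 75th percentile moved the median change of all genes from 0.04 to -0.13 and the share of calls that were higher from 50.5% to 37.3%, so small changes depend on the scaling.

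**Figure D2:**
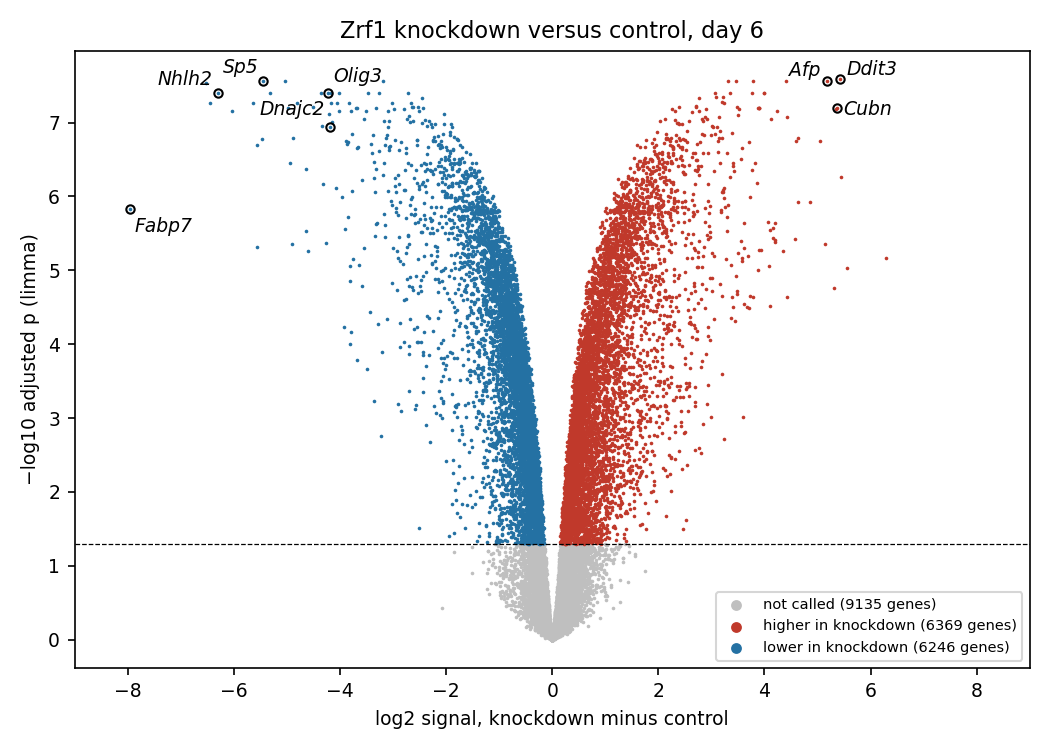
Log2 change (knockdown minus control, horizontal) against -log10 of the limma adjusted p (vertical) for 21750 genes, with 6369 called higher in red, 6246 called lower in blue and the others in grey. Circles mark genes named in the text, and the dashed line is an adjusted p of 0.05.

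The 10 largest falls among genes with a current symbol were taken by the fitted change. For a probe dim on knockdown arrays that change and its limma p include signal not above background. Its rank among the falls is therefore not settled, and its p is not exact. Fabp7 (probe on chromosome 10 from 57508039 to 57508098, mm9) had a log2 signal of 2.82 ± 0.08 in control arrays and was not well above background on any knockdown array (limma adjusted p = 1.50e-06). The helix-loop-helix factor Nhlh2 was at least 19.6-fold lower, the forkhead factor Foxb1 at least 25.5-fold, the long non-coding RNA Rmst at least 23.5-fold and the Hes family member Hes3 at least 15.3-fold, with limma adjusted p values from 3.96e-08 for Nhlh2 to 4.36e-06 for Hes3. Prdm13, a spinal cord and hindbrain regulator, and Sp5, a target of Wnt signalling, stayed measurable in all knockdown arrays and were 47.4-fold and 43.5-fold lower (limma adjusted p = 2.03e-07 and 2.79e-08). The protocadherin Pcdh8 was lower (limma adjusted p = 4.84e-06) and was well above background on 1 of the 4 knockdown arrays, so no exact fold is given. Pcdhb21 was at least 6.47-fold lower (limma adjusted p = 1.61e-07), but it belongs to a clustered protocadherin family, so its probe cannot be assigned to it with certainty. Dach2 was at least 8.67-fold lower with its brighter probe (limma adjusted p = 3.96e-08). Without control 2, 3 or 4 another probe of Dach2 stood for the gene, and the change was -1.37, -1.39 and -1.38 with limma adjusted p values of 0.0552, 0.0537 and 0.0536.

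The 10 largest rises among genes with a current symbol were taken in the same way, with the same limit for probes dim on control arrays. Ddit3, which encodes the stress factor CHOP (probe on chromosome 10 from 126732518 to 126732821, mm9), went from -0.79 ± 0.10 to 4.63 ± 0.07 (limma adjusted p = 2.56e-08). The proteoglycan gene Srgn rose 41.0-fold. Cubn rose 41.4-fold and was well above background on 3 of the 4 control arrays. Clic5 was at least 17.2-fold higher, Habp2 at least 15.5-fold, the kinase gene Stk32a at least 16.6-fold, the Hedgehog ligand Dhh at least 10.9-fold and Fer1l4 at least 7.84-fold, none of them well above background on any control array, with limma adjusted p values from 1.79e-07 for Fer1l4 to 9.35e-06 for Clic5. The histone gene H3c15 was higher (limma adjusted p = 4.36e-06) and was well above background on 1 control array, so no exact fold is given. It is 1 of many near-identical histone H3 genes, so its probe cannot be assigned to that copy with certainty.

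Neural progenitor genes formed the list with the clearest fall. The median change over its 36 tested members was -1.58, or -1.49 with 3 genes that were dim in 1 group set at their bound, and the list was called lower by camera, with an estimated correlation too (adjusted p = 0.00528 with an estimated correlation). Hes5 went from 5.12 ± 0.08 to 1.10 ± 0.13, Olig3, a dorsal progenitor factor, fell 18.6-fold, the zinc finger factor Zic1 fell 11.1-fold and the growth factor Ptn fell 9.08-fold. Within the slides the median of the list was -1.60, -1.65 and -1.40. Named after their values were seen, the neural factors Sox1 and Sox2 fell by 2.39 and 1.24, and the intermediate filament Nes by 0.98. Lhx2, Nkx6-1 and Lix1 were the 3 members that rose, Lix1 at the edge of the threshold (limma adjusted p = 0.0499). Pax6, a marker of radial glia, did not pass the test with its brighter probe (-0.24, limma adjusted p = 0.0961), and its other tested probe was called higher.

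Of 33 neuronal genes 19 fell and 7 rose, and the list was called lower by camera (adjusted p = 0.00319), a call lost with an estimated correlation (adjusted p = 0.140 with an estimated correlation). Tagln3 fell 14.6-fold and Ebf3 3.48-fold, while the microtubule regulator Stmn2 rose 4.75-fold. Restricting the test to probes above background on all 8 arrays, which removes genes lost in 1 group, ended the call of the neuronal list (adjusted p = 0.0610). Among 10 glial genes 6 rose and 2 fell (camera adjusted p = 0.0490, and adjusted p = 0.280 with an estimated correlation). Of its tested members, Apoe rose 3.69-fold, Aldoc 3.28-fold and Cnp 2.55-fold, and these 3 genes are also expressed outside glia. Gfap, S100b, Olig1, Olig2, Cspg4 and Sox8, also on the glial list, were not well above background on all arrays of either group and were not tested. The glial call ended under 18 alternatives, among them the knockdown pairs averaged (adjusted p = 0.0510) and 7 in which any 1 array other than knockdown 3 was left out, which put its adjusted p between 0.0539 and 0.0688.

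Signalling lists of the neural tube fell in part. In the Notch list 10 of 15 genes fell and 3 rose (camera adjusted p = 0.00319, and adjusted p = 0.283 with an estimated correlation), with Dtx4 8.09-fold, the ligand Dll1 3.80-fold and the receptor Notch3 2.67-fold lower. In the Hedgehog list 7 of 12 fell and 1 rose (camera adjusted p = 0.00186, and adjusted p = 0.0677 with an estimated correlation). The co-receptors Boc and Gas1 were 5.96-fold and 4.87-fold lower and the transducer Smo 2.65-fold, although 1 of the 2 Smo probes was not called. Cdon, another co-receptor, had 1 probe called lower (-1.18) and 1 called higher, and the mean of both changed by 0.11 (limma adjusted p = 0.182). Of 28 Wnt ligands and receptors 14 fell and 6 rose (camera adjusted p = 0.0309, and adjusted p = 0.415 with an estimated correlation). Wnt3 was at least 6.39-fold lower (limma adjusted p = 5.43e-08) and its receptor family member Fzd10 16.6-fold lower. The Wnt ligand and receptor call ended with probes above background on all 8 arrays (adjusted p = 0.0631), without knockdown 3 and 4 (adjusted p = 0.0520) and with the arrays of slide 2 alone (adjusted p = 0.0605), an alternative chosen after the data were seen. Wnt targets and antagonists fell in 13 of 22 cases and rose in 6 (camera adjusted p = 0.0181, and adjusted p = 0.425 with an estimated correlation). Besides Sp5, they included Cdx1, the cyclin Ccnd1 and Myc, which changed by -3.42, -3.26 and -2.51.

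The list of BMP and TGF-beta targets, which also holds ligands and antagonists, split. Of its genes 8 of 19 were higher and 4 lower, and the list was not called (camera adjusted p = 0.388). Msx1 fell 18.4-fold while the ligand gene Bmp2 rose 3.82-fold and Ccn2 2.11-fold. The retinoic acid list split as well, with 5 of 19 higher and 8 lower (camera adjusted p = 0.148), and its members Nr2f1 and Nr2f2 fell 4.74-fold and 3.98-fold. With the number in the file name as a random block the adjusted p of the list was 0.0392, from the pre-ranked form of camera.

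Hox genes, which set position along the body axis, fell as a group. Of 29 tested, 19 fell and 4 rose, with a median change of -1.36, and the camera call (adjusted p = 7.72e-05) was lost with an estimated correlation (adjusted p = 0.0834 with an estimated correlation). Hoxb5 fell 13.1-fold, Hoxb6 8.98-fold, Hoxb4 4.35-fold and Hoxa3 3.37-fold. The lists of regional brain markers moved both ways and were not called. Of 10 forebrain and midbrain genes 3 rose, among them Lhx2 by 0.90 and Otx2 by 0.61, and 3 fell (camera adjusted p = 0.883). Of 14 hindbrain and spinal cord genes 6 rose and 6 fell (camera adjusted p = 0.883). The motor neuron factor Phox2a rose 8.95-fold and the progenitor factor Dbx1 7.68-fold, whereas Irx5 fell 3.07-fold. Neural crest genes were higher in 6 of 17 cases and lower in 9 (camera adjusted p = 0.676). Msx1, which is on this list too, fell 18.4-fold, while Sox10 rose 4.09-fold and Ets1 5.33-fold.

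Pluripotency genes moved both ways. Of 28 tested, 9 rose and 15 fell, and the list was not called (camera adjusted p = 0.0640), though it passed under 4 alternatives, with adjusted p values from 0.00122 to 0.0478. The lowest came from the random block, with the pre-ranked form of camera. Prdm14 fell 10.4-fold and was well above background on 3 of 4 knockdown arrays, Nanog fell 5.44-fold with 1 of its 2 probes called, Nr5a2 fell 4.97-fold and Esrrb 3.42-fold. Pou5f1, the core pluripotency factor, named after its values were seen, changed by -0.33 and did not pass the test (limma adjusted p = 0.139). Of 13 epiblast genes 6 rose and 6 fell (camera adjusted p = 0.749). Pou3f1 rose 3.33-fold, and the cadherin Cdh2, the Wnt effector Lef1 and the Nodal antagonist Lefty1 fell 4.69-fold, 2.50-fold and 4.20-fold. Among 32 Polycomb genes, which repress transcription through histone marks, 7 rose and 15 fell (camera adjusted p = 0.0953, and 0.0302 with no filter on dim probes). Bmi1 fell 4.47-fold, Phf19 3.98-fold and the methyltransferase Ezh2 2.20-fold, and Pcgf5 rose 2.70-fold.

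Endoderm genes formed the list with the clearest rise. The median change over 26 tested members was 1.53, or 1.51 with 2 genes dim in 1 group at their bound, and the camera call held with an estimated correlation (adjusted p = 0.0380 with an estimated correlation). Afp went from below background on all control arrays to -0.89 ± 0.11 (limma adjusted p = 2.79e-08), and the endodermal factors Gata6 and Gata4 rose 8.84-fold and 7.21-fold, with Gata4 well above background on 3 of 4 control arrays. Within the slides the median of the list was 1.48, 1.52 and 1.52. Foxa1 was the member that fell (-0.66) and Foxa3 the one not called, both named after their values were seen.

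**Figure D3:**
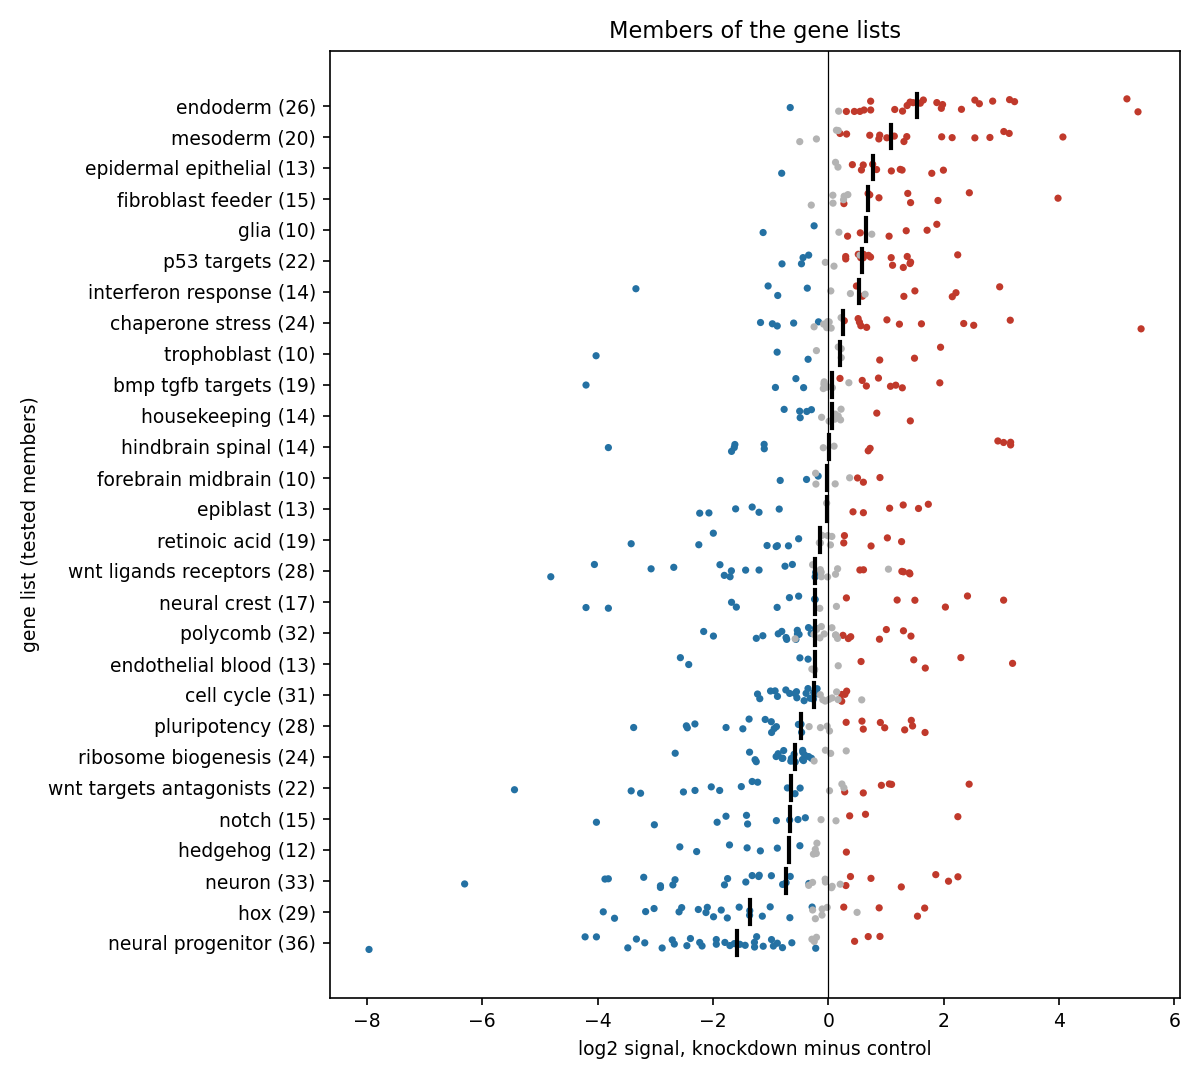
Log2 change (knockdown minus control) of each tested member of the 28 gene lists, with the number of members in parentheses, red for called higher, blue for called lower and grey for not called, and a black bar at the median of the list. The neural progenitor list has the lowest median, -1.58, and the endoderm list the highest, 1.53.

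Among the lists of other non-neural cell types, camera called mesoderm, fibroblast and epithelial genes higher at its preset correlation, and none of the 3 calls held with an estimated correlation. In the mesoderm list 16 of 20 tested genes rose and none fell (camera adjusted p = 7.72e-05, and adjusted p = 0.129 with an estimated correlation). The rest of its 30 genes, among them T, Mixl1, Mesp1 and Hand1, were not well above background on all arrays of either group and were not tested. The cardiac actin gene Actc1 rose 8.80-fold and Snai1 3.91-fold. Myl7 and Pdgfra rose too (limma adjusted p = 2.21e-06 and 1.84e-07), but were well above background on 2 and 1 of the control arrays, so no exact fold is given. Of 15 fibroblast or feeder genes 9 rose and none fell (camera adjusted p = 0.00165, and adjusted p = 0.0765 with an estimated correlation). Thy1 rose 15.8-fold, Tagln 3.74-fold and the collagen genes Col1a1 and Col5a1 2.69-fold and 2.60-fold. Epithelial genes rose in 10 of 13 cases and fell in 1 (camera adjusted p = 0.00267, and adjusted p = 0.0834 with an estimated correlation), with Krt19 3.99-fold, Esrp1 3.47-fold and Krt18 2.13-fold higher. Endothelial and blood genes moved both ways, 5 of 13 higher and 4 lower (camera adjusted p = 0.845). Runx1, well above background on 3 of 4 control arrays, rose 9.16-fold, Gata1 4.92-fold and Flt1 3.21-fold, and the embryonic globin Hbb-bh1 fell 5.35-fold. Of 10 trophoblast genes 3 rose and 3 fell (camera adjusted p = 0.854). Cdx2 fell 16.3-fold and was well above background on 3 of 4 knockdown arrays, and Esx1 rose 3.86-fold.

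Targets of the tumour suppressor p53 rose in 15 of 22 cases and fell in 4 (camera adjusted p = 0.00319, and adjusted p = 0.0677 with an estimated correlation). The pro-apoptotic genes Pmaip1 and Bbc3 rose 4.74-fold and 2.13-fold, Btg2 2.46-fold and Perp 2.17-fold. Trp53, which encodes p53 and was looked up after the list was seen, fell by 1.59 (limma adjusted p = 2.05e-06). Genes of ribosome biogenesis fell in 20 of 24 cases and none rose (camera adjusted p = 7.51e-06, and adjusted p = 0.0677 with an estimated correlation). Pes1 fell 6.30-fold with 1 of its 2 probes called, Nop56 2.38-fold, Rrs1 1.87-fold and nucleolin, Ncl, 1.71-fold. Of 31 cell cycle genes 18 fell and 5 rose (camera adjusted p = 0.0123, and adjusted p = 0.237 with an estimated correlation). The replication genes Rrm2, E2f1, Ccne1 and Mcm5 fell by 1.19, 1.23, 0.88 and 0.92. The cell cycle call ended under quantile normalization (adjusted p = 0.104) and with the authors' values (adjusted p = 0.0872).

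The chaperone and stress list was not called (camera adjusted p = 0.0640), though it passed under 3 alternatives, with adjusted p values from 0.000492 to 0.0476. The lowest came from the random block, with the pre-ranked form of camera. Of the 24 genes of the list 12 were higher and 5 lower. Beside Ddit3, Atf3 rose 8.91-fold, Trib3 5.09-fold and Chac1 3.06-fold. Interferon response genes moved both ways, 7 of 14 higher and 4 lower (camera adjusted p = 0.254), with Bst2 4.44-fold and Cxcl10 4.64-fold higher and Oasl2 10.1-fold lower. Of 14 housekeeping genes 2 rose, 5 fell and 7 were not called (camera adjusted p = 0.883). B2m rose 2.68-fold and Pgk1 1.79-fold, the latter with a probe placed on chromosome 3 while the gene lies on X, so its signal cannot be assigned to Pgk1 with certainty, and Sdha fell 1.70-fold and Hprt 1.41-fold. Gapdh and Actb, named after their values were seen, changed by 0.01 and 0.17 and did not pass the test (limma adjusted p = 0.908 and 0.0918), but the brightest Gapdh probe, which gave that value, is placed on chromosome 7 while the gene lies on chromosome 6. The probes of Gapdh disagree: of its 8 tested probes, 5 placed on chromosome 6 were called lower, with changes from -0.68 to -0.43, as was 1 placed on chromosome 8, and the other 2, 1 on chromosome 6 and the one on chromosome 7, were not called.

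Of the 28 lists, camera called 6 higher and 9 lower at its preset correlation, and 2 of these 15 calls held with an estimated correlation. Some lists share genes, so these calls are not independent. Counts adjusted over the list alone equalled those over all genes in 24 lists. The others, adjusted over the list alone, were 7 higher and 20 lower for neurons, 12 and 0 for fibroblasts, 5 and 6 for endothelium and blood, and 8 and 4 for interferon response. Tested with fry, whose p asks whether the genes of a list move one way on balance without comparison to other genes, 27 lists passed, and its mixed p, for change in either direction, passed in 28. Median, mean and test differed in sign for the forebrain and midbrain, trophoblast, endothelium and blood, and housekeeping lists, none of them called by camera. The median of each of the 15 called lists had the same sign on all 3 slides. The names of the scanner files leave open that the knockdown arrays come from fewer cultures than arrays, and with those pairs averaged, 4 against 2, limma called 10935 genes, 10844 of them with the direction found with 4 against 4.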

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

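The check of single arrays was planned, and the leave-one-out counts below were planned too. In groups of 4 arrays, a value was picked when its gap to the nearest other array took up an unusually large part of the range of the group, a rule that chance meets in about 1 of 20 groups (5%). It picked 14 of 260 groups, or 5.38%, so the number as a whole is near that of chance.

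Control 3 held 7 of the 14 values. There Rmst was at 0.82, above the 0.50 to 0.52 of the other control arrays, Cdx1 at 4.11, above 3.68 to 3.75, Cdon at 3.47, above 3.22 to 3.25, Chac1 at 1.72, above 1.44 to 1.46, and Cxcl10 at -1.96, above -2.41 to -2.36. Cdh2 at 4.79 and Hoxb5 at 2.83 lay below the other control arrays, which reached 5.28 and 3.14. Knockdown 1 held 4 values. H3c15 at 0.45, Prdm13 at -1.52 and Phox2a at 3.06 lay above the other knockdown arrays, and Rrs1 at 1.96 lay below them. The remaining 3 were Msx1 at 4.05 on control 4, below the 4.34 to 4.39 of the others, Dll1 at -0.78 on knockdown 2, above -0.85, and Hprt at -2.99 on knockdown 3, below -2.83 to -2.80. Each of these gaps was smaller than the change of the gene between the groups. Without control 3 the counts were 6283 higher and 6264 lower, and without knockdown 1 they were 5962 and 6114, against 6369 and 6246 with all arrays.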

How the results depend on the processing

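The alternative with slide 2 alone was chosen after the data were seen. Dnajc2 kept its direction and its call under every alternative run, and ranged from -4.39 to -4.00 over the fits that left out arrays. Its change was smaller with normexp (-3.47) and with the authors' values (-3.49), and the cause was not tested. The counts of 6369 genes higher and 6246 lower stayed within 1.5 times under all but 2 alternatives. Median scaling gave 4156 higher and 6981 lower, since it shifted the median of all genes to -0.13, and the threshold of at least 2-fold gave 2260 and 1622 by its own construction. Leaving out arrays gave 5263 to 6283 higher and 5073 to 6264 lower. The medians of the 15 called lists kept their direction under the other scalings, but not always their size. With the authors' values that of mesoderm went from 1.08 to 0.48, of fibroblasts from 0.69 to 0.42, of glia from 0.65 to 0.32, of the cell cycle from -0.25 to -0.15 and of Wnt ligands and receptors from -0.22 to -0.14. With normexp those of mesoderm and glia were 0.63 and 0.39, and with quantile normalization that of the cell cycle was -0.16. Leaving out control 2 or knockdown 1 alone also lowered that of glia, to 0.415 and 0.417. Median scaling, which lowers all genes alike, moved those of the cell cycle and of Wnt ligands and receptors the other way, to -0.42 and -0.39. The cause of the other shifts was not tested. Lists called higher and lower, 6 and 9, became 1 and 1 with an estimated correlation and 12 and 15 with fry, which asks another question. Averaging the knockdown pairs gave 5406 higher and 5529 lower, with 2 fewer residual degrees of freedom, and the 2 slide 2 arrays per group alone gave 4635 and 4534.

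Label numbers did not pair the arrays: deviations of arrays with the same number correlated at -0.19 to 0.11 across probes, while arrays of 1 slide in different groups correlated at 0.11 to 0.32. Some arrays correlated better with one of another number on the same slide than with that of their own number. With the label number as a replicate block 5767 genes were higher and 5640 lower, Dnajc2 had the same change of -4.19 and 5 lists were higher and 9 lower. The glial list lost its call there (adjusted p = 0.0542).

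Of 3175 values of 123 named genes under the alternatives, 3162 kept direction and call, 12 lost the call and 1 turned. The 1 that turned was Cdon with the mean of its probes, at 0.11, because its probes disagree. Those that lost the call were Dach2 in 3 settings, Hprt on slide 2 alone and Lmx1b, a call near the threshold, in 8. Of 728 list values 695 kept their side, 24 lost and 9 gained a call. The losses were mostly of the glial list, and pluripotency, stress, Polycomb or retinoic acid lists gained one in some settings. The cause was not tested where none is given. Signal over background limits the fold of genes dim in 1 group: 175 genes were above background in control arrays only and 271 in knockdown arrays only.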

Other observations

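The search over gene families below, the comparison of endoderm with other non-neural lists, and the test of slide with the arrays of slide 2, were chosen after the results were seen, and the other tests were set out before theirs.

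Gene families grouped by the opening letters of their symbols, some of which share genes with the fixed lists, were searched with camera over 171 families of at least 10 tested genes. It called 5 families higher and 11 lower, none of which held with an estimated correlation (lowest adjusted p = 0.509 with an estimated correlation). Genes of the major histocompatibility complex with H2 symbols rose in 15 of 17 cases and fell in 2 (camera adjusted p = 0.00129, and adjusted p = 0.509 with an estimated correlation). The class II genes H2-Ab1, H2-Eb1 and H2-Oa rose by 1.82, 1.58 and 2.44 on the log2 scale and the class I gene H2-K1 by 1.08. The median of the family was 1.06, and 0.89 under median scaling. Genes of this family are similar in sequence, so signal shared between their probes was not separated. Annexins rose in 9 of 10 cases (camera adjusted p = 0.00927, and adjusted p = 0.509 with an estimated correlation), with Anxa3 at 2.06, Anxa1 at 1.64 and Anxa2 at 1.40.

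Of 36 DEAD-box helicase genes with Ddx symbols 25 fell and 3 rose (camera adjusted p = 0.00481), of 35 Rbm genes 23 fell and 3 rose (0.00927), of 20 nucleoporins 14 fell and 1 rose (0.0105), of 14 Integrator subunits 11 fell and none rose (0.0105), and of 11 SR splicing factors 9 fell and 1 rose (0.0315), and all 5 had an adjusted p of 0.509 with an estimated correlation. Srsf6 fell by 2.08 and Srsf1 by 1.06. Ribosomal protein genes went the other way, with 55 of 85 higher and 1 lower (camera adjusted p = 0.000254, and adjusted p = 0.795 with an estimated correlation). Their median was small, 0.28 against 0.04 for all genes, and 0.11 against -0.13 under median scaling and 0.07 against 0.01 under quantile normalization. The directions of all families named here were the same under median and quantile scaling, normexp and the authors' values.

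The first pattern weighed was the share of 58% of genes called. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many genes, the real one with 12615, and the highest of the others gave 192. Splits that mix the groups carry the group difference in their residual spread, which lowers their calls. They also ignore slide, so this comparison alone does not exclude chance. The split with 192 genes, slide 2 against slides 1 and 3, had been planned as a test of slide. It can show a difference between slides, but holds both groups on each side and so cannot show slide as the origin of the group difference. The 2 control and 2 knockdown arrays of slide 2 alone, between which slide cannot differ, called 9169 of 23419 genes, against slide as the origin. Averaging possible repeat arrays left 10935 genes, the lowest count over 4 other scalings was 11137, and probe GC content explained 0.406% of the variance of changes. These values argue against those repeat arrays, the scaling and probe GC content as the origin of most calls. They cannot show a technical difference that ran with the group, such as in the preparation of the RNA. What also stays open is whether the 4 arrays of a group stem from separate cultures, and a difference between the cell lines from before the knockdown. The labels do not say whether 1 or several hairpins or clones were used, so effects of a hairpin on genes other than Zrf1 stay open too. An effect of Zrf1 loss is therefore a hypothesis.

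The second pattern was the rise of endoderm, mesoderm and epithelial lists with the fall of the neural progenitor list. A mere lower share of progenitors would raise the markers of all other cell types alike. The mean of the endoderm list lay 2.22 above that of the pluripotency list (SE of the difference over genes 0.373), 1.96 above that of neural crest (0.550) and 1.82 above that of trophoblast (0.587). The 3 lists were chosen after the changes of the lists were seen. The mesoderm, fibroblast and epithelial lists, with mean changes of 1.36, 0.96 and 0.78, were not among them. These differences therefore cannot decide whether a mere lower share is the whole cause. Their SE treats genes of a list as independent, and whether progenitors themselves carry transcripts of these lists was not checked. Of 4 list medians, 0 turned under 4 other scalings, of which median scaling shifts all genes alike by too little to turn them. That of mesoderm, 1.08, was 0.63 with normexp and 0.48 with the authors' values. A separate list of 20 primitive and visceral endoderm genes, none in a fixed list, had a median of 0.58 with 11 higher and 2 lower, as a primitive or visceral endoderm programme in the knockdown arrays would give, though camera did not call it (adjusted p = 0.0645). Of these genes 17 were above background on all control arrays, and 7 passed the test in neither direction, Ctsl and Rhox5 among them with changes of 0.17 and 0.10. More cells of that kind, or the same genes rising within progenitors, may both lie behind it, and a list of 7 definitive endoderm genes had 3 higher, 3 lower and a median of -0.08.

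The third pattern was the rise of Ddit3, Atf3, Trib3 and Chac1. A wider integrated stress response had a median of -0.0482 over 28 other ATF4 targets, 10 higher and 11 lower, with Nupr1 at 2.07 and Slc6a9 at -1.76. Further heat shock genes had a median of 0.13 (6 of 14 higher, 4 lower) and endoplasmic reticulum chaperones 0.25 (8 of 15 higher, 3 lower). The median of the ATF4 targets lay below the bound set beforehand against a wider response. Its SE over genes, 0.156, left that unsettled, an allowance that the bound as written did not include. The medians of the heat shock genes and of the chaperones lay between the bounds set beforehand. None of these 3 is therefore decided here.

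A gain or loss of a whole chromosome in 1 of the lines was also tested: the autosome farthest from the median of all genes was chromosome 13, at -0.0722, inside the bound of 0.2 set beforehand, which argues against it. Permuting genes over chromosomes gave chromosome 13 an adjusted p of 0.0315, the only one of 21 chromosomes under 0.05, so a small shift of its genes is left unexplained.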
